A study of Homo sapiens with 6 samples.

How the data were processed

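Total RNA of THP-1 cells was sequenced in 6 libraries, 3 after a negative control microRNA mimic and 3 after a miR-125a-5p mimic, 24 h after transfection, per the labels. The authors deposited 1 table of raw counts per gene for the 6 libraries, with 26347 gene identifiers. The values are whole numbers with no normalization. Per the submitters' processing notes, bcl2fastq, TopHat and edgeR were used with the genome build hg19, with no versions. The counting tool, gene annotation, strand setting and treatment of reads that match several genes are not given in the sources used here. Reads of overlapping or antisense genes and of near-identical copies therefore cannot be told apart in these counts. Each column was matched to its library by the name the labels give it, and 0 columns belonged to no library. The identifiers matched whole-number gene identifiers of a RefSeq gene table on GRCh38.p14, used for names only, for 26204 rows (99.5%) that held 99.8% of the counts. There were 0 blank and 0 duplicated identifiers.

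Depth ran from 8256149 to 10257791 counts per library, and the 10 most abundant genes took 6.78% to 8.03% of them. Replicate libraries were compared by a chi-square statistic per gene against sampling noise, over genes with a mean count of at least 20. It lay between 4.01 and 12.0 for pairs within a group, so no pair agreed within sampling noise and all 6 libraries were counted as separate samples. For pairs of libraries from different groups it lay between 5.14 and 13.4. The ranges overlap, so this measure did not separate the libraries by treatment. Pairs that held control library 1 had the highest values, 9.90 to 13.4, and all other pairs lay between 4.01 and 7.29. The common biological coefficient of variation was 12.5%.

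Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (14731 of 21274 with any count), library sizes were scaled by the trimmed mean of M-values, and glmQLFit and glmQLFTest were run with the package default and no covariate. The first fit run used the option legacy = FALSE. It was replaced by the package default after its output had been seen, and both gave 0 higher and the same 4 lower genes. P-values were adjusted by Benjamini-Hochberg, with 0.05 as the threshold. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are scaled by the same factors and given as mean ± SD of 3 libraries.

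Gene lists (28, fixed before the data were examined, as were the tests, the groups and the alternatives not named as added) were tested with camera of limma 3.58.1, with a correlation of 0.01, on log2 CPM with a prior count of 2, for the 22 lists with at least 5 tested members. The mitochondrially encoded list had 0 rows in the table and the 5 lists of other cell types had too few tested genes, so these 6 were not tested. Camera with an estimated correlation and fry were alternatives. The text names the 10 largest rises and falls among called genes with a mean CPM of at least 5 and no overlap of groups, the 5 smallest p in each direction, up to 4 called members of each list (8 for reported miR-125 targets) or up to 2 members with the smallest p where none was called, and the 5 called falls with the smallest p among genes with an 8mer. Names outside this rule are stated as such.

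Sites were searched in the longest annotated 3′ UTR of at least 20 bases of each gene in GENCODE 29, on GRCh38, which differs from the build used for the counts. Of the tested genes 12791 (86.8%) had one, and the others were left out as not searched. The classes were 8mer CTCAGGGA, 7mer-m8 CTCAGGG, 7mer-A1 TCAGGGA and 6mer TCAGGG, each gene counted under its best site. The median difference of a class was taken from genes holding no 6mer, whereas camera tested the class against all other searched genes. The seed 7mer was ranked among 7mers found in 0.75 to 1.25 times as many genes. The steps were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 200 genes of at least 5 CPM changed in each of 3 runs. For 14731 genes, 45.8% of changes of 0.5 on the log2 scale were recovered, 88.6% of changes of 1 and 99.5% of changes of 2, with 25 calls among unchanged genes over the 3 runs. With 200 changed genes the Benjamini-Hochberg threshold is easier to pass than in the real comparison, which called 4. Recovery there may therefore be lower. A shift of -0.1 put into genes with an 8mer came back as -0.12, and with no shift put in the difference was 0.016. Genes were drawn independently, so these values leave out correlation between genes.

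Alternatives covered normalization, the count filter, the test (DESeq2 1.42.0, limma voom, edgeR's likelihood ratio test, glmTreat against a fold of 1.2), the threshold, each library left out, the replicate number as a block, the shortest 3′ UTR and sites in the coding sequence. Removal of the GC trend of each library (loess, span 0.5), legacy = FALSE and the seed test under DESeq2 size factors were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.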

Results

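RNA sequencing libraries were made from THP-1 cells, an established human monocytic leukaemia line, 24 h after transfection with a synthetic microRNA. The study's title speaks of macrophages, but the sample labels name no differentiation step, so the cell state is in doubt and the labels were followed. The mimic was either a negative control or miR-125a-5p, a microRNA whose seed (bases 2 to 8) pairs with complementary sites in the 3′ untranslated regions (3′ UTRs) of messenger RNAs. Each group had 3 libraries. Control libraries 1, 2 and 3 held 10257791, 8423228 and 9040297 counts, and miR-125a-5p libraries 1, 2 and 3 held 8537658, 9356861 and 8256149. Control library 1 stood apart from the other 5 on the first principal component of log2 CPM, at -38.2 against 1.14 to 16.3. CPM are counts scaled to the library's total after adjustment by the trimmed mean of M-values. The first component held 25% of the variance and component 5 held 16.5%, so the variance was spread widely. On the second, which held 21.2%, miR-125a-5p library 3 stood apart at 31.1 against -21.5 to 5.24. The row of the microRNA's own precursor gene, MIR125A, held 1 count in all 6 libraries together, in control library 3. A transfected mimic is not made from that gene, so this row does not check the labels. The sources did not say that the libraries came from separate cultures or days, and p-values then measure only the spread between these libraries, which may be technical.

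The first comparison asked which transcripts differed after transfection with the miR-125a-5p mimic. By edgeR's quasi-likelihood test, transcripts of 4 genes fell and 0 rose, while 397 genes were higher at an unadjusted p under 0.05 and DESeq2 called 2 higher. LIPA, which encodes the lysosomal acid lipase that splits cholesteryl esters and triglycerides, fell from 226 ± 51.1 CPM (SD, n = 3) to 111 ± 11.7 CPM (SD, n = 3). SLC37A2, a sugar-phosphate exchanger of the endoplasmic reticulum abundant in macrophages, fell from 133 ± 25.7 to 72.3 ± 8.35 CPM. BIN2, a membrane-bending BAR-domain protein of blood cells, went from 82.1 ± 7.30 to 46.8 ± 5.76 CPM, and NPL, the N-acetylneuraminate lyase that breaks down sialic acid, from 42.3 ± 3.05 to 22.8 ± 6.0 CPM.

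The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over 14731 genes gave LIPA a log2 fold change of -1.03 (SE 0.12, adjusted p = 0.000203), a level 51.1% lower. By the same edgeR test SLC37A2 had -0.88 (SE 0.12, adjusted p = 0.00206), BIN2 -0.81 (SE 0.12, adjusted p = 0.00224) and NPL -0.89 (SE 0.16, adjusted p = 0.0395). All 4 were lower in each miR-125a-5p library than in each control library, with raw counts between 135 and 2902 per library. Such separation of the groups was seen in 1651 genes, 11.2% of those tested, where chance gives 10%. Control library 1 had the highest level of LIPA (285 CPM) and of SLC37A2 (158 CPM). With 1 library left out, the log2 fold change was -1.14 to -0.83 for LIPA and -1.01 to -0.73 for SLC37A2. NPL lost its call without control library 2 (adjusted p range over the alternatives 7.44e-06 to 0.335), and likewise without miR-125a-5p library 2 or 3 in the edgeR fits, while 14 genes were lower without control library 3. The numbers of calls depended on the test: DESeq2 called 2 higher and 11 lower, and edgeR's likelihood ratio test 4 higher and 17 lower.

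**Figure D1:**
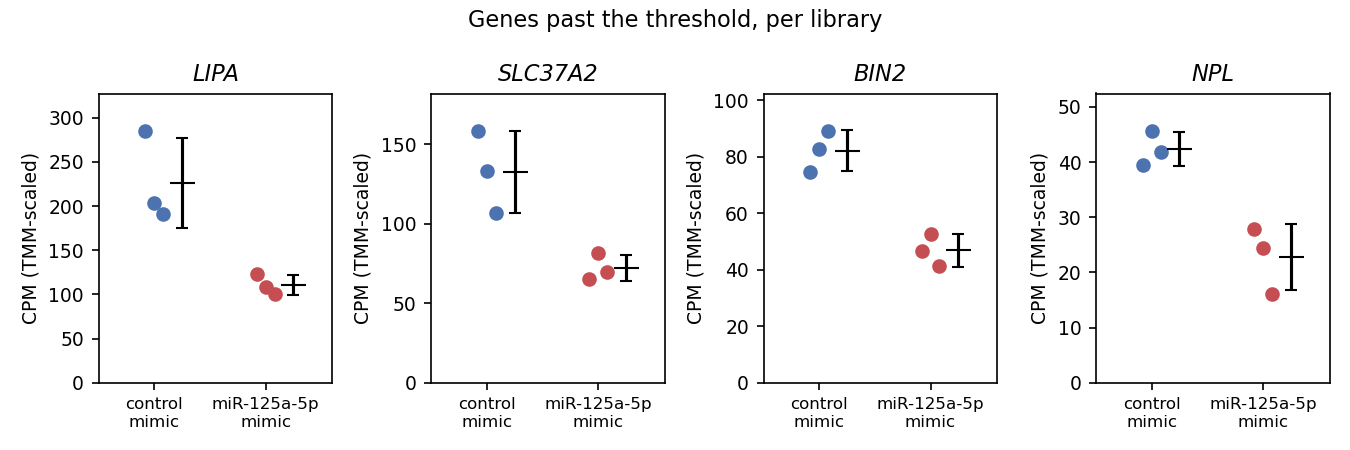
CPM scaled by trimmed mean of M-values (y axis, from 0) of LIPA, SLC37A2, BIN2 and NPL in the 3 control mimic libraries (blue points) and the 3 miR-125a-5p mimic libraries (red points), with the mean and SD of each group beside the points. The miR-125a-5p libraries lay between 100.4 and 123 CPM for LIPA, below the lowest control library at 191.

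The next genes did not pass. TGFBR2, the type II receptor of TGF-beta, had the next smallest p among the falls, with a log2 fold change of -0.53 (SE 0.10, adjusted p = 0.0767 by edgeR). Among rises the smallest edgeR adjusted p was 0.136, for APBA1, an adaptor of the amyloid precursor protein, at 14.6 ± 0.779 CPM in control and 24.7 ± 1.11 CPM in miR-125a-5p libraries. GPD1L (log2 fold change 0.70), HRH1, a histamine receptor (0.84), CANX, the chaperone calnexin of the endoplasmic reticulum (0.35), and BAHD1, a chromatin protein (0.72), had edgeR adjusted p of 0.172, 0.225, 0.296 and 0.310. At an unadjusted p under 0.05 there were 397 higher and 475 lower genes, 872 in all, where chance alone would give 736.55. Splits of the same libraries that mixed the groups gave 390 to 1017 such genes, 3 of them more than the real split, so this count does not set the treatment apart.

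The mimic's seed was compared with the 3′ UTRs annotated in GENCODE release 29 on GRCh38. LIPA, BIN2 and NPL each carried 1 copy of the full 8-base site CTCAGGGA in the longest annotated 3′ UTR, and SLC37A2 carried only the 6-base core TCAGGG there. In the coding sequence the best match was a 7mer-A1 for SLC37A2, an 8mer for BIN2 and a 6mer for NPL, and LIPA had none. The 8-base site was in 3 of 3 annotated 3′ UTRs of LIPA, 3 of 4 of BIN2 and 4 of 5 of NPL. The LIPA gene lies on the minus strand of chromosome 10 from 89213569 to 89414557 (GRCh38). Its site is at 89213857 to 89213864, in the last of 9 exons, within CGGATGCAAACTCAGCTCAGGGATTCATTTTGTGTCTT. BIN2 lies on the minus strand of chromosome 12 from 51281038 to 51324668, with the site in the 3′ UTR of exon 13 of 13 at 51281278 to 51281285, within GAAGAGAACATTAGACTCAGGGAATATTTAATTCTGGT. NPL lies on the plus strand of chromosome 1 from 182789293 to 182830384, with the site in the 3′ UTR of exon 10 of 10 at 182828974 to 182828981, within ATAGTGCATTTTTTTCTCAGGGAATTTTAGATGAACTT. SLC37A2 spans 125063067 to 125090312 on the plus strand of chromosome 11, and its 6-base match is at 125088340 to 125088345 in the 3′ UTR of exon 19 of 19. Sites were also found among the rises named above, none of which passed. The best site was a 7mer-m8 for APBA1, which held 4 sites of 7 or 8 bases, and for HRH1. It was a 7mer-A1 for GPD1L, and CANX and BAHD1 had no 6-base match.

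The second comparison asked whether genes with a seed site differed as a class. Genes with an 8mer site in the 3′ UTR (768 genes) were lower after the miR-125a-5p mimic than genes with no 6-base match (8017 genes), by a median log2 difference of -0.079, and 61.5% of them had a negative fold change against 46.5% of genes with no match. Genes whose best site was the 7mer-m8 CTCAGGG (1325 genes) had a difference of -0.043, those with the 7mer-A1 TCAGGGA (1020 genes) -0.025 and those with the 6mer alone (1661 genes) -0.0042. Only the 8mer class passed in limma's camera test with a preset correlation (two-sided, adjusted over 4 classes, adjusted p = 0.0141). Each class was set there against all other searched genes, so camera's p-values do not test the differences from genes with no match. Camera's adjusted p was 0.0765 for the 7mer-m8 class, 0.700 for the 7mer-A1 class and 0.870 for the 6mer class, whose camera direction was up. With an estimated correlation the 8mer class did not pass (camera adjusted p = 0.197).

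In single libraries, set against the mean of the control libraries, the 8mer difference was -0.070, -0.091 and -0.037 in miR-125a-5p libraries 1, 2 and 3, a mean of -0.066 ± 0.027 (SD, n = 3). Each control library, set against the other controls, lay between -0.029 and 0.022. Control values lie around 0 by this construction. The miR-125a-5p values share the same control mean, so their SD leaves out the error of that mean. The two-sided exact permutation p over the 6 libraries was 0.1, the smallest that 3 against 3 libraries allow. Among genes lower at an unadjusted p under 0.01, 24 of 113 had an 8mer (21.2%, against 5.87% of the other searched genes, odds ratio 4.32, 95% confidence interval 2.62 to 6.90), and among genes higher at that p 5 of 79 had one (6.33%). Genes are not independent replicates, so these shares describe these libraries. Without control library 1 or 2, or miR-125a-5p library 1 or 2, the 8mer class had camera adjusted p of 0.0686, 0.0587, 0.0675 and 0.160, with differences from -0.074 to -0.058.

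**Figure D2:**
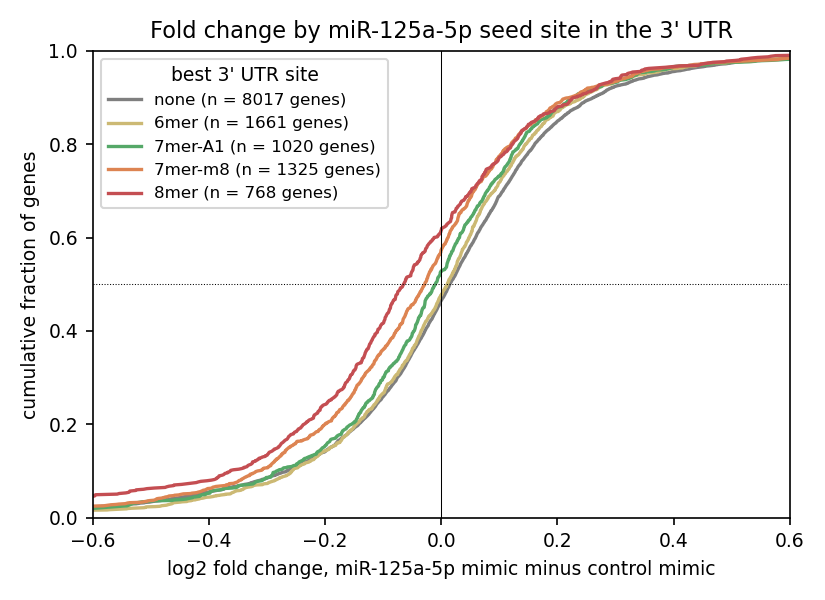
Cumulative fraction of genes (y axis) at or below each log2 fold change, miR-125a-5p minus control mimic (x axis, shown from -0.6 to 0.6), by the best seed site in the longest annotated 3′ UTR. The curve of the 768 genes with an 8mer lies left of the curve of the 8017 genes with no site around the median, with medians of -0.065 and 0.015.

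**Figure D3:**
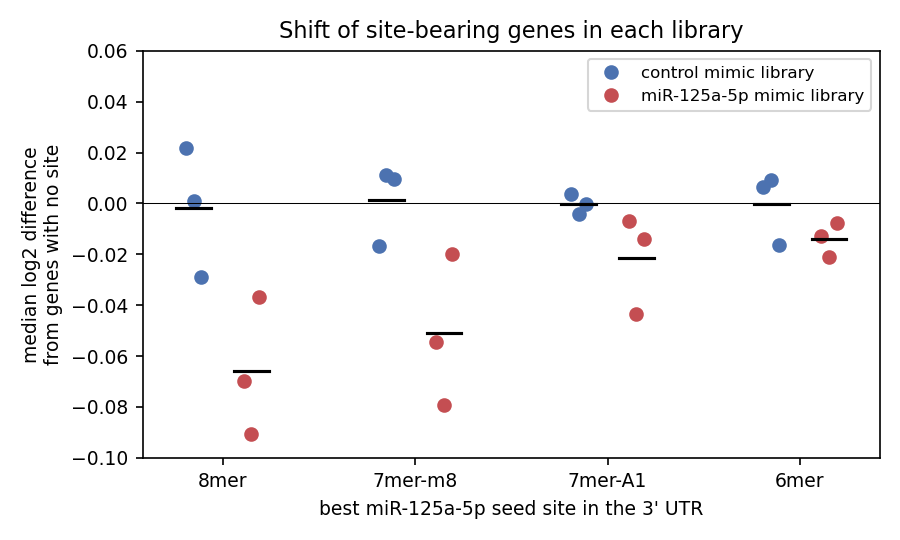
Median log2 difference from genes with no site (y axis) for each class of site (x axis) in each library, as blue points for control and red points for miR-125a-5p libraries, with the group mean as a black line. A miR-125a-5p library is set against the mean of the 3 controls and a control library against the other controls; for the 8mer the miR-125a-5p libraries lie from -0.091 to -0.037 and the controls from -0.029 to 0.022.

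The seed 7mer CTCAGGG was also ranked among all 7mers found in a like number of 3′ UTRs. Its genes (2093) had a median difference of -0.055 from genes without its 6-base core, and 0 of 4468 other 7mers had a lower one. The nearest was TCTCAGG, which overlaps the site, at -0.053. Among the 515 other 7mers with the same number of G and C bases the lowest was GCTCAGG at -0.041. Their median was -0.024, so part of the seed's difference was shared by 7mers of like composition.

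The third comparison asked whether groups of genes fixed before the data were examined differed. Of 22 lists tested with camera at the preset correlation, 6 passed, and 0 of the 6 passed with an estimated correlation. Splits of the libraries that mixed the groups called 0 to 4 lists at the preset correlation. A call at this setting therefore does not by itself set the treatment apart. Genes reported as targets of the miR-125 family were lower: 37 of 48 measured members had a negative fold change, with a median log2 fold change of -0.21 (camera adjusted p = 1.38e-05, and adjusted p = 0.302 with an estimated correlation). None of the 48 passed the edgeR test over all genes, and 4 were lower when adjusted over the list alone. These were LACTB, a mitochondrial protease-like protein (39.4 ± 6.34 to 24.4 ± 5.11 CPM, log2 fold change -0.69), TNFRSF1B, a receptor of tumour necrosis factor (105 ± 8.04 to 77.6 ± 11.5 CPM, -0.44), the pro-apoptotic BAK1 (37.4 ± 10.4 to 24.8 ± 3.90 CPM, -0.60), and the transcription factor ETS1 (68.9 ± 4.95 to 48.9 ± 12.8 CPM, -0.49). BAK1 and ETS1 lay outside the rule for naming genes of this list and were chosen after their values were seen. Both carried an 8mer, TNFRSF1B a 7mer-A1 and LACTB a 6mer, so this list and the 8mer class share genes. The log2 fold change of BAK1 was -0.36 without control library 1, and that of ETS1 was -0.30 without miR-125a-5p library 3.

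Interferon-stimulated genes were lower as a list, with a negative fold change in 37 of 37 members and a median of -0.15 (camera adjusted p = 1.38e-05, and adjusted p = 0.565 with an estimated correlation). None passed singly, either over all genes or adjusted over the list alone. Of 10 splits of the libraries, 3, the real one among them, had a median as large in size. The largest in a split that mixed the groups was 0.18, so this median does not set the treatment apart. IFI27 had a log2 fold change of -0.42 (106 ± 25.2 to 79.1 ± 7.68 CPM) and ISG20, an exonuclease, -0.49 (45.3 ± 12.2 to 32.2 ± 4.43 CPM), and control library 1, which stood apart on the first component, had the highest level of both. Without control library 1 the log2 fold change of IFI27 was -0.21. The BCL2 family of apoptosis regulators was lower, with 14 of 15 members negative, a median of -0.21 and 1 member, BAK1, lower when adjusted over the list alone (camera adjusted p = 0.0127, and adjusted p = 0.565 with an estimated correlation). Without control library 1 or miR-125a-5p library 2 the BCL2 family did not pass (camera adjusted p = 0.240 and 0.0600). Its members BAK1, BMF, MCL1 and BCL2 were also on the list of reported miR-125 targets and carried an 8mer, so these results are not separate. MCL1 and BCL2 lay outside the rule for naming genes.

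Higher as lists were genes of the G2 and M phases of the cell cycle, of cholesterol synthesis and of the heat shock response. In the G2 and M list 28 of 36 members had a positive fold change, with a median of 0.10 (camera adjusted p = 0.00534, and adjusted p = 0.565 with an estimated correlation), and CCNB1, cyclin B1, stood at 65.0 ± 2.78 and 80.2 ± 3.07 CPM. In the cholesterol synthesis list 19 of 25 were positive, with a median of 0.11 (camera adjusted p = 0.0199, and adjusted p = 0.565 with an estimated correlation). FDFT1, squalene synthase, had 404 ± 9.77 and 491 ± 46.3 CPM, and INSIG1, a sterol sensor of the endoplasmic reticulum, 79.1 ± 9.90 and 97.2 ± 9.65 CPM. In the heat shock list 11 of 12 were positive, with a median of 0.12 (camera adjusted p = 0.0375, and adjusted p = 0.565 with an estimated correlation), and the mitochondrial chaperone HSPD1 had 619 ± 62.3 and 756 ± 66.5 CPM. No member of these 3 lists passed the edgeR test, over all genes or adjusted over the list alone. Leaving out miR-125a-5p library 2 ended the calls of all 3 (camera adjusted p = 0.130, 0.0507 and 0.388), and leaving out control library 1 ended those of the G2 and M list (0.231) and the heat shock list (0.115). Without control library 2 the cholesterol list (0.150) and the heat shock list (0.0695) did not pass, without miR-125a-5p library 3 the cholesterol list did not (0.301), and without control library 3 or miR-125a-5p library 1 the heat shock list did not (0.0612 and 0.0504).

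**Figure D4:**
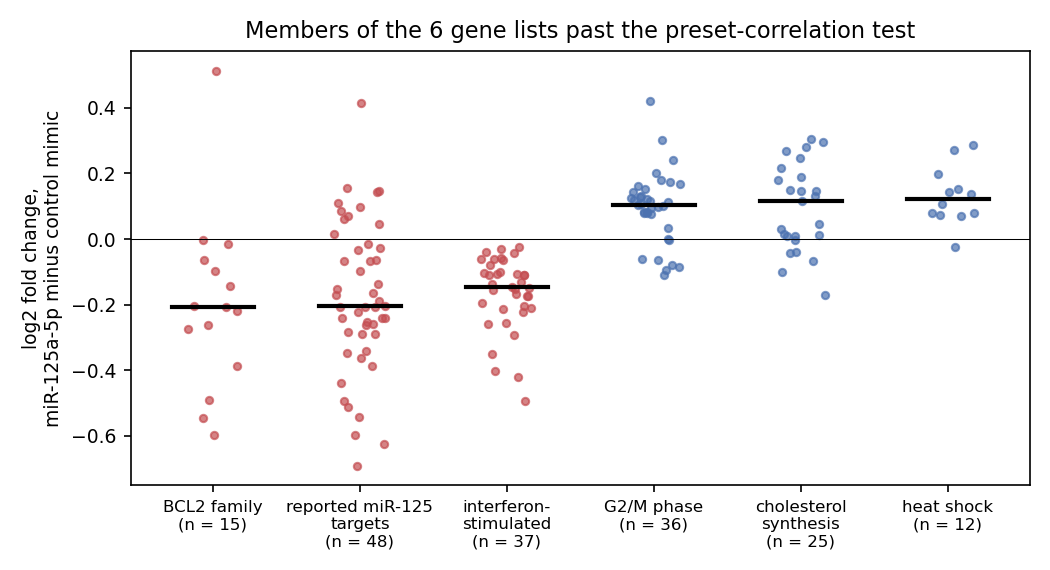
Log2 fold change, miR-125a-5p minus control mimic (y axis), of each measured member (points) of the 6 lists past camera's threshold at the preset correlation (x axis, with the number of members), with the median as a black line. All 37 interferon-stimulated genes lie below 0, and 11 of 12 heat shock genes lie above it.

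The other 16 lists tested did not pass. LIPA was the 1 called member of both the lipid uptake and efflux list (16 of 25 negative, camera adjusted p = 0.223) and the lysosome and autophagy list (22 of 37 negative, 0.200). In the list of NF-kB-driven cytokines (17 of 27 negative, camera adjusted p = 0.189), CXCL10, an interferon-induced chemokine, was lower when adjusted over the list alone, at 129 ± 43.2 and 74.5 ± 15.5 CPM, with a log2 fold change of -0.80 that was -0.51 without control library 1. Macrophage differentiation genes (25 of 36 negative) and nuclear genes of oxidative phosphorylation (28 of 39 positive) both had camera adjusted p = 0.0716. The first passed without control library 3 (camera adjusted p = 0.0150, up to 0.307 without another library) and the second without control library 1 (0.000443, up to 0.709), so neither result held against the loss of 1 library. CD86, a costimulatory receptor of the first list, had a log2 fold change of -0.62 with an edgeR adjusted p of 0.555. Toll-like receptor signalling (19 of 32 negative) had camera adjusted p = 0.223, with its adaptor TICAM2 at a log2 fold change of -0.55. In the S phase list, adjusted over the list alone, FEN1, a flap endonuclease, was lower (110 ± 6.12 to 83.3 ± 6.14 CPM) and RRM2, a ribonucleotide reductase subunit, higher (348 ± 29.5 to 428 ± 22.2 CPM), with camera adjusted p = 0.976 for the list. In the list of unfolded protein and amino acid stress genes, also at camera adjusted p = 0.976, CANX was higher and DDIT4, an inhibitor of mTOR signalling (13.6 ± 3.13 to 7.22 ± 1.85 CPM), lower when adjusted over the list alone.

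The remaining lists gave camera adjusted p of 0.976 for class II antigen presentation, 0.635 for microRNA machinery, 0.599 for glycolysis, 0.582 for immature myeloid genes, 0.436 for p53 targets, 0.346 for ribosomal proteins, and 0.276 each for hypoxia response and immediate early genes, with 0 members called. Camera's direction was up where the median was negative for class II antigen presentation, immature myeloid genes, S phase, and unfolded protein stress, and in the last pair the mean was negative too. For glycolysis the median was positive and the mean negative.

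Markers of other cell types were summed as CPM. These sums used library totals without the trimmed mean of M-values factors. Markers of T and natural killer cells summed to 56.0 ± 3.54 CPM in control and 51.0 ± 4.95 CPM in miR-125a-5p libraries, and those of fibroblasts and endothelium to 317 ± 10.2 and 310 ± 30.4 CPM. Nearly all of the last sum came from PECAM1, an adhesion molecule that monocytes also express (315 ± 9.74 and 307 ± 28.5 CPM), which was chosen after its values were seen. B cell markers summed to 71.0 ± 16.0 and 50.9 ± 10.1 CPM, nearly all from PAX5, a transcription factor of B cells (67.0 ± 16.5 and 47.3 ± 9.87 CPM, edgeR adjusted p = 0.501), which was lower when adjusted over its list of 2 tested genes alone. Its log2 fold change of -0.51 was -0.33 without control library 1. Erythroid and megakaryocyte markers summed to 0.416 ± 0.360 and 0.974 ± 0.405 CPM, and epithelial markers to 0.397 ± 0.588 and 0.0404 ± 0.0699 CPM.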

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

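Removal of the GC trend, legacy = FALSE and the seed test under DESeq2 size factors were chosen after seeing the data. The 4 called genes were also called under DESeq2 size factors, upper quartile, library size only, a CPM filter, limma voom, GC trend removal and legacy = FALSE, with 0 higher and 4 lower in each. LIPA, SLC37A2 and BIN2 passed in 18 of 18 alternative fits at 0.05. Their highest adjusted p, by the test of each fit, were 0.00593, 0.0489 and 0.0465. NPL passed in 14 of 18, not against a minimum fold of 1.2 (3 lower) or in 3 fits with a library left out. In the main fit 3 genes were lower at an adjusted p under 0.01. With no count filter 11 genes were higher and 41 lower, with DESeq2 2 and 11 (4284 genes had no adjusted p), and with the likelihood ratio test 4 and 17. Leaving out 1 library gave 0 to 2 higher and 3 to 14 lower, from fewer samples, with the 14 without control library 3 and the 2 higher without miR-125a-5p library 3. The replicate numbers did not pair the libraries (correlations of deviations 0.056, 0.014 and -0.016; only number 1 matched best with its own number), and with the replicate block 0 were higher and 9 lower, the heat shock list had camera adjusted p = 0.0549, and no other passing list or site class lost its call.

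Of the lists, 6 passed, 0 with an estimated correlation, 0 with fry, 9 with voom weights and 2 to 9 with 1 library left out, the 2 without miR-125a-5p library 2. Reported miR-125 targets and interferon-stimulated genes passed camera without each library in turn (highest adjusted p 0.00149 and 0.0402). Lists that had not passed and turned direction did so without passing. These were class II antigen presentation (adjusted p = 0.948 with fry, 0.952 with voom weights, 0.829 with the replicate block, 0.556 to 0.9998 with 1 library left out) and S phase (0.948 with fry, 0.554 to 0.9998 with 1 library left out). With 1 library left out the range was 0.142 to 0.971 for immature myeloid genes, 0.0316 to 0.921 for immediate early genes, 0.0290 to 0.971 for ribosomal proteins and 0.645 to 0.9998 for unfolded protein stress, and those under 0.05 kept their direction. Lists that gained a call did so without control library 3 (macrophage differentiation 0.0150, lipid uptake and efflux 0.0329, NF-kB-driven cytokines and immediate early genes 0.0316 each), without control library 1 (oxidative phosphorylation 0.000443, ribosomal proteins 0.0290), without miR-125a-5p library 1 (ribosomal proteins 0.0430) or with voom weights (macrophage differentiation 0.0189, oxidative phosphorylation 0.0326, lysosome and autophagy 0.0493), by camera adjusted p.

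The 8mer difference was -0.086 to -0.058 with 1 library left out, and -0.044 for sites in the coding sequence, where it did not pass (camera adjusted p = 0.385). The 7mer-m8 difference was -0.060 to -0.036, and passed without miR-125a-5p library 3. The 7mer-A1 difference was -0.037 to -0.017, lowest without miR-125a-5p library 3 and highest without miR-125a-5p library 2, and passed in neither. The 6mer difference was -0.014 to 0.0014, above 0 without control library 2. The cause was not tested for these changes. In counts simulated at this depth and group size, with 200 genes changed per run, 45.8% of changes of 0.5 on the log2 scale were recovered. Other depths, group sizes and numbers of changed genes were not simulated.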

Other observations

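The tests of list calls and list medians in other splits, and the removal of the GC trend, were chosen only after the results were seen. DESeq2 called 9 genes that edgeR's quasi-likelihood test did not: CMKLR1, GPD1L, ZNF385A, GBP1, APBA1, IL10RA, NEU1, PTPRJ and TGFBR2. Values are given for IL10RA and PTPRJ, chosen after their values were seen, and for TGFBR2, which the naming rule gave. IL10RA, a receptor chain of interleukin 10, had 122 ± 6.0 CPM in control and 86.1 ± 0.110 CPM in miR-125a-5p libraries (edgeR adjusted p = 0.0767, DESeq2 adjusted p = 0.00158). PTPRJ, a receptor tyrosine phosphatase, had 285 ± 21.0 and 207 ± 11.9 CPM (edgeR adjusted p = 0.0870, DESeq2 adjusted p = 0.00170). TGFBR2 had 115 ± 4.07 and 80.2 ± 6.41 CPM (DESeq2 adjusted p = 0.00158). IL10RA and PTPRJ carried a 7mer-m8 site and TGFBR2 no 6-base match in the longest annotated 3′ UTR. APBA1 and GPD1L, which were higher, carried a 7mer-m8 and a 7mer-A1 there.

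The lower level of genes with an 8mer was set against base composition, length and abundance. In a regression across genes on GC content of the 3′ UTR and transcript, both lengths and mean log2 CPM, the 8mer difference was -0.065 (SE 0.010 over genes, which are not replicates) and it was -0.060, -0.074 and -0.055 in the single miR-125a-5p libraries, which argues against these properties as the whole of the difference. After that adjustment 2 of 4468 other 7mers ranked lower than CTCAGGG. These were TCTCAGG, which overlaps the site, and TCAGGGA, the 7mer-A1 site of the same seed. The seed 7mer then stood at -0.041, against a median of -0.012 for other 7mers of equal GC count. The real split of the libraries had the largest 8mer difference, 1 of 10 splits, at 0.079 against at most 0.052 in another, and 1 of 10 with as many called genes, 4 against at most 0. A total of 10 splits is too few for a share under 0.05. Repression through the seed may account for the difference, as a hypothesis that these splits leave open.

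Features of the site were tested as hypotheses. Genes with at least 2 sites of 7 or 8 bases (850) were lower than genes with 1 (2263) by -0.022 (SE 0.010) after adjustment, consistent with a larger response to more sites, although site class was not held fixed. Among genes with a single 8mer, those with more A and T around the site (221 against 225) differed by 0.012 (SE 0.027), so no larger response was seen. Genes with a 7mer for the natural passenger strand, miR-125a-3p (2365 against 6974), differed by 0.0021 (SE 0.0060), which gives no sign that this sequence acted. The test cannot speak to a mimic whose passenger strand has another sequence.

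GC-rich transcripts had lower fold changes, with a slope of -0.025 log2 units per 10 points of GC (SE 0.0025, across genes). Without miR-125a-5p library 1 the slope was 0.0024 (SE 0.0028), consistent with a trend that needs that library, whose own slope was -0.068. Other libraries moved it too: the slope was -0.012 (SE 0.0028) without control library 2 and -0.054 (SE 0.0027) without miR-125a-5p library 3, whose own slopes were 0.039 and 0.044. The 4 called genes passed after the trend was removed.

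The real split called 6 lists, 1 of 10 splits with as many, against 0 to 4 in the others. Only the split with control library 1 and miR-125a-5p libraries 1 and 3 on one side called 0. For reported miR-125 targets the real median of 0.21 in size was the largest, 1 of 10 splits, against at most 0.13. For interferon-stimulated genes 3 of 10 splits had a median as large as the real 0.15, the largest being 0.18 with control libraries 1 and 2 and miR-125a-5p library 1 on one side. With 10 splits no share under 0.05 can be reached.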
